A study of Vulpes lagopus with 12 samples.

How the data were processed

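Blood RNA of Arctic foxes (Vulpes lagopus), a wild canid of the far north, was measured on Affymetrix Canine Genome 2.0 arrays, whose probes were designed against the dog. Per the labels' protocols, blood was collected in tubes that stabilise RNA, RNA was extracted with a kit for such tubes, and a university core facility prepared the biotin-labelled target and ran the arrays. The series holds 12 arrays: 11 of foxes, and 1 whose title calls it a canine control. The organism label of that array reads Vulpes lagopus and its source and tissue labels read blood cells and blood, as for the foxes, so what RNA it carried beyond its title is not given in the sources used here. Foxes are numbered 1 to 11 in the order in which the series lists them.

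The deposited values were on a log2 scale and were made by the authors with RMA (background correction, quantile normalization and a summary per probe set) in Affymetrix Expression Console, per the submitters' processing notes. The versions of both, and whether the 12 arrays were normalized together, are not given in the sources used here. The table held 43035 probe sets with 0 missing values, from 3.23 to 15.64. It gave no detection call or background level, so no floor could be set for low values. Of these, 111 were Affymetrix control probe sets, which served only to look at RNA and hybridisation quality, and 42924 were tested. In the probe annotation 29254 tested probe sets had 1 gene symbol, 439 had several and 13231 had none. Genes were read from the first of these classes, 15115 in all, each by the probe set with the highest mean over all arrays. The symbols of 13382 of them also stood in the Arctic fox RefSeq annotation. No genome positions are given, since the probes target dog sequence.

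The exposure of single foxes to polychlorinated biphenyls (PCBs) or mercury was not in the labels, so foxes were not grouped. The labels gave no batch and did not state that the 11 samples came from 11 animals; if some did not, the spread between foxes is partly technical.

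The following choices were made before the data were examined. The control array was compared with the 11 foxes by limma (lmFit and eBayes), with Benjamini-Hochberg adjusted p-values over all tested probe sets and a threshold of 0.05. With 1 control array the fit assumes that it varies as the foxes do. An exact permutation test of 1 array against 11 cannot give a p below 0.0833. Each fox was compared with the other foxes in the same way. A total of 27 gene lists were fixed: 7 of contaminant and oxidative responses, 10 of blood cell types, and 10 of general cell programs. Per list, the median control minus fox difference was set against 10000 random lists of the same size matched on mean expression, and a list in the outer 5% was counted as shifted. The mean pairwise Pearson correlation of a list's genes over the foxes was set against 10000 random lists in the same way (one-sided), with Benjamini-Hochberg adjustment over the 27 lists. Its p, called random-list p here, is the share of random lists at least as correlated, and no foxes were permuted for it. A list score was the mean of its genes' log2 values, each centred on its fox mean. The 70 pairs of an exposure and a cell list were tested by two-sided permutation of Pearson's r with 100000 resamples. A probe set was counted as variable when its SD over the foxes was at least 0.5.

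Named genes followed a rule. For the control array they were the 12 genes with the largest positive and the 12 with the largest negative log2 difference among those with an adjusted p under 0.05 and a control value outside all 11 foxes. For the spread between foxes they were the 20 genes with the largest SD among genes whose fox mean was above that of the median gene. Placeholder symbols were left out. A further 17 genes of contaminant and oxidative responses were named whatever their value, and up to 4 members per list with the largest difference or SD. The ribosomal and oxidative phosphorylation lists were read from symbol prefixes; kinases and assembly factors that share those prefixes were kept out, a departure from the literal rule.

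The alternatives were probe sets with a mean above that of the median probe set, quantile normalization again, centring each array on its median, limma with trend and robust settings, an absolute log2 difference of at least 1, the range of the foxes in place of limma, the mean of all probe sets of a gene, Spearman correlation, random lists also matched on SD, genes scaled to SD 1, the mean in place of the median of a list, another measure or threshold of spread, and each fox left out in turn. Leaving out foxes 9, 10 and 11, leaving out fox 2, and removing the first principal component were chosen after seeing the data. So were exact permutation tests within foxes 1 to 8 of the 70 pairs, also after each rescaling, and of the 27 list scores against the SD of all values on an array, and 14 lists of organ marker genes, of which 13 had measured genes.

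Both tests were tested on simulated data. With 50 probe sets planted per step on 1 array, limma recovered 14 at a log2 difference of 1, 42 at 2, 48 at 4 and 46 at 6, and it called 5 unchanged probe sets. The list test called 20 of 20 lists planted at a correlation of 0.3 and 2 of 80 random ones. Outside the planted lists the simulated genes varied independently of each other. In the foxes, random lists matched to the ribosomal list had a median correlation of 0.18, so the simulated rates need not hold for the data. R 4.3.3 with limma 3.58.1 and python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.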

Results

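Gene expression was measured in blood of the Arctic fox on 12 arrays, 11 of foxes and 1 of a canine control. The design statement names polychlorinated biphenyls (PCBs), persistent industrial pollutants, and mercury as what the fox blood cells were examined for. Array medians lay between 7.06 and 7.17 for the foxes and at 6.85 for the control, on the log2 scale. The number of arrays limits the precision, and the control had no replicate.

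The control array against the foxes asks which genes of canine control RNA lay outside the levels of fox blood. Among the genes with the largest differences, those known from liver, gut and muscle were higher on the control array, and several known from neutrophils were lower. CLCA4, an intestinal gene of the chloride channel accessory family, stood at 4.49 ± 0.13 (SD, n = 11) in the foxes and at 14.30 on the control, a log2 difference of 9.81 (SE 0.15). ALB, the serum albumin of the liver, stood at 6.58 ± 0.20 (SD, n = 11) against 15.30, a difference of 8.71 (SE 0.21). ALAS2, the haem synthesis enzyme of red cell precursors, went the other way, from 13.23 ± 1.53 (SD, n = 11) to 6.57, a difference of −6.66 (SE 1.45). By limma with Benjamini-Hochberg adjustment the adjusted p was 2.22e-13 for CLCA4, 5.23e-12 for ALB and 0.0022 for ALAS2, and the control lay outside all 11 foxes for each.

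The other genes with the largest positive differences were of the same organs or of fat and kidney. The fatty acid carrier FABP4, abundant in fat cells, differed by 9.65, and the peptidase ENPEP of intestinal and kidney membranes by 9.08. MYH2, a fast muscle myosin, differed by 9.01, and FGG, a fibrinogen chain made in the liver, by 8.78. The stomach pepsinogen PGA differed by 8.56, the intestinal retinol carrier RBP2 by 8.46 and the peptide transporter SLC15A1 by 8.40. CYP2E1, a liver cytochrome P450, differed by 8.31, the amino acid transporter SLC1A1 by 8.31 and the intestinal sucrase SI by 8.20. SEs in this group were between 0.12 and 0.29.

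Among the genes with the largest negative differences, several are known from white blood cells. The calcium-binding proteins S100A8 and S100A9 of neutrophils and monocytes differed by −5.75 (SE 0.74) and −5.01 (SE 1.17). PGLYRP1, a peptidoglycan-binding protein of neutrophil granules, differed by −5.01, the myeloid signalling adaptor TYROBP by −4.98, and the Fc receptor FCGR1A by −4.49. EMB differed by −5.74, CDK12 by −5.61, RP2 by −5.51, CYRIA by −4.54, RIPOR2 by −4.51 and PTPRE by −4.31. Adjusted p-values by limma for these lower genes lay between 3.13e-05 and 0.0057.

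**Figure D1:**
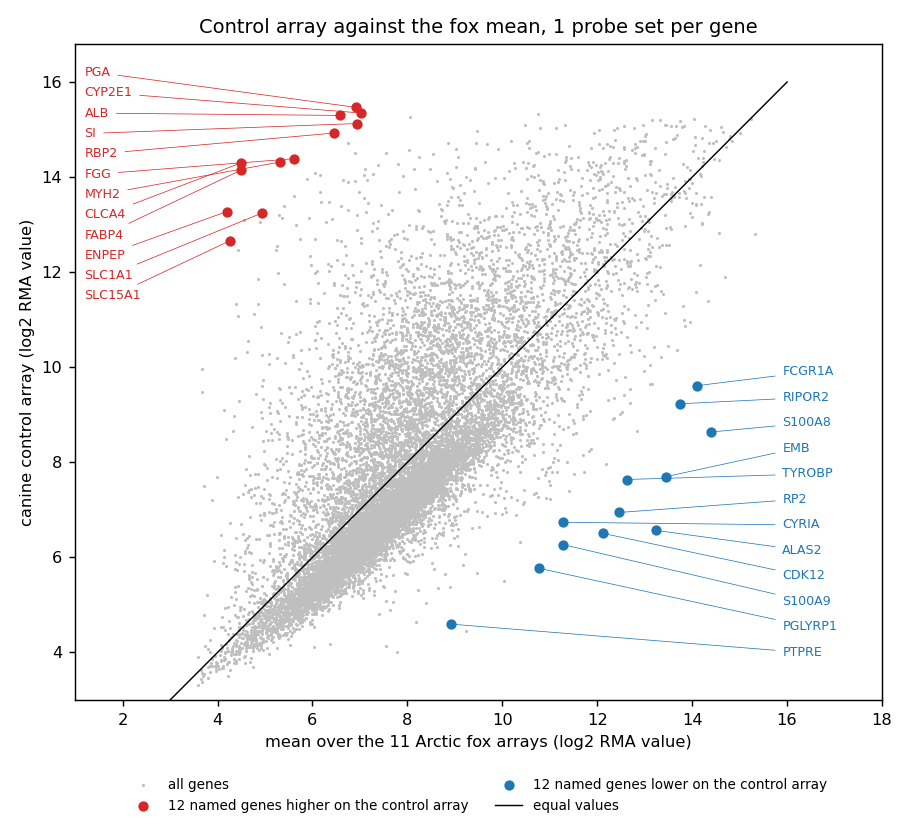
Each point is 1 gene, with the mean over the 11 fox arrays on the x axis and the canine control array on the y axis, both as log2 RMA values. Genes such as CLCA4 and ALB lie far above the diagonal, and ALAS2 and S100A8 far below it.

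In total limma called 26183 of 42924 probe sets, 8092 higher and 18091 lower on the control. With an absolute log2 difference of at least 1 the majority turned, to 6637 higher and 5179 lower, and with arrays centred on their medians 9348 were higher and 9914 lower. The median difference over probe sets was −0.46 as deposited. Of 15115 genes, 9547 were called (2799 higher and 6748 lower), and 9113 of these lay outside all 11 foxes. The control's correlation with single foxes, across probe sets, ran from 0.684 to 0.764, against 0.900 to 0.990 between foxes. The control is 1 array with fox organism and blood labels, so the comparison describes that array, not 2 species, and its p-values rest on the spread between foxes.

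Groups of contaminant response genes lay high on the control array for drug-metabolising enzymes and chaperones. Liver and gut genes were also high there, so the exposure lists cannot be read on this array as a response to contaminants. The 7 lists held 113 measured genes, of which 41 were called higher, 24 lower and 48 were not called; adjusted over the list alone, 39 were higher and 22 lower. Targets of the nuclear receptors CAR and PXR, which govern hepatic drug metabolism, had a median difference of 4.05, above all 10000 matched random lists. Of their 8 genes, 7 were higher and 1 lower, with CYP3A26 at 8.04, the drug efflux pump ABCB1 at 6.96 and CYP2B6 at 5.05. Heat shock and unfolded protein genes had a median of 1.63, with 8 higher, 1 lower and 10 not called (6 and 0 adjusted over the list alone). After quantile normalization again the median was 0.66, still above the outer bound of random lists. The mitochondrial chaperonin HSPD1 differed by 3.60 and HSPA2 by 3.55.

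Antioxidant lists moved less and in both directions. Selenoproteins had a median of 0.61 (percentile 98.64 of random lists), with 9 higher, 3 lower and 8 not called; with the mean of all probe sets per gene the median was 0.01 (percentile 90.31) and the shift was lost. After quantile normalization again it was 0.15 (percentile 98.78), and with low-level genes left out 1.08 (percentile 98.62). The plasma selenium carrier SELENOP differed by 6.94 (SE 0.33) and the deiodinase DIO1 by 5.92, while the methionine sulfoxide reductase MSRB1 differed by −3.30, which was not called with arrays centred on their medians (adjusted p by limma 0.0584). NRF2 and glutathione genes had a median of 0.35 (percentile 98.47), with 7 higher, 6 lower and 15 not called (7 and 5 adjusted over the list alone). GCLM, a subunit of the enzyme that starts glutathione synthesis, differed by 5.70, catalase (CAT) by 5.02 and SOD1 by 4.17. The NRF2 median turned to −0.13 after quantile normalization again, and to −0.18 with the mean of all probe sets per gene. The first of these values still lay above the outer bound of random lists (percentile 97.58) and the second did not (86.8). The NRF2 shift was also lost with low-level genes left out (percentile 92.5), without fox 9 (0.35, percentile 97.37) and without foxes 9, 10 and 11 (0.40, percentile 96.71). The remaining exposure lists were not shifted, and their medians and means had opposite signs. These were the AhR battery (−0.28 and 0.45), genes of the dioxin receptor, metallothionein and zinc handling (−0.59 and 1.17), and thyroid and retinoid receptors (−0.32 and 0.72). By the mean, the latter 2 lists were shifted. The metallothionein median also turned to 0.15 with the mean of all probe sets per gene, and the AhR median to 0.02 without foxes 9, 10 and 11. Of the AhR genes 2 were higher and 3 lower, of the metallothionein list 4 and 4, and of the thyroid and retinoid list 4 and 6. Single members were still far apart: the metal-binding MT2A differed by 6.46 and MT1E by 5.96, the thyroid hormone carrier TTR by 7.31, the retinol carrier RBP4 by 7.07 and CYP1A2 by 4.51.

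**Figure D2:**
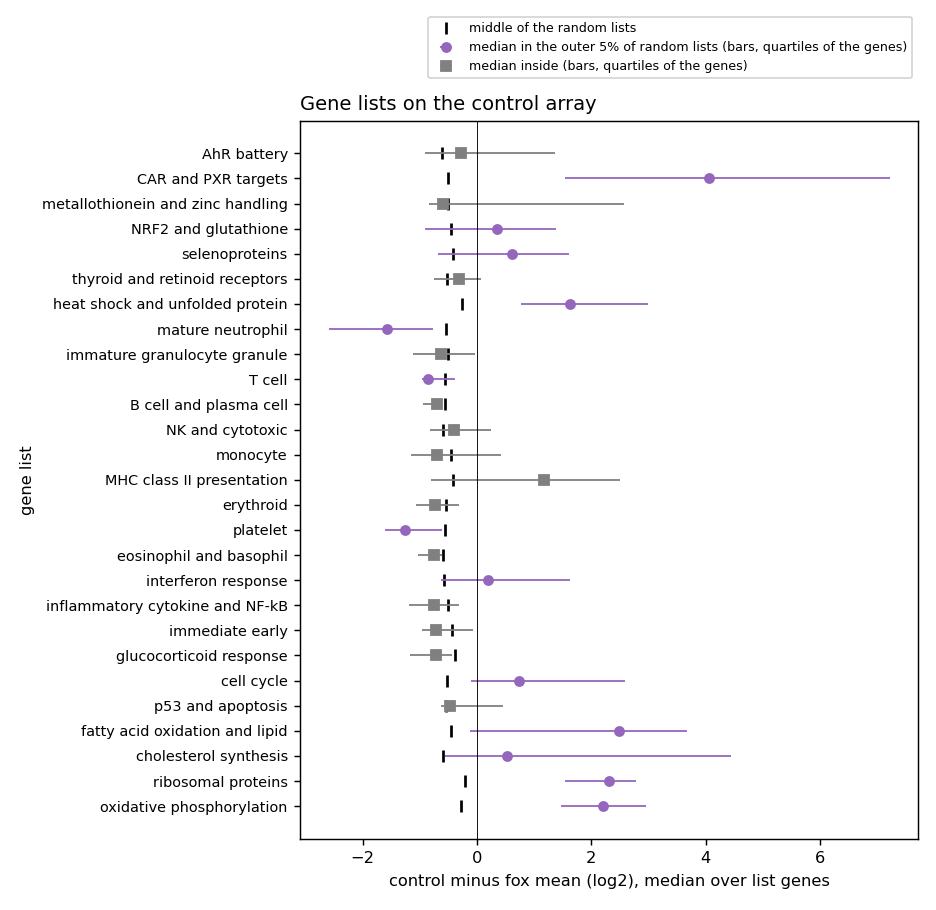
Points give the median control minus fox difference (log2) of each of the 27 gene lists, and black ticks the middle of 10000 matched random lists. CAR and PXR targets lie highest at 4.05 and mature neutrophil genes lowest at −1.58.

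Of the blood cell lists, those of neutrophils, platelets and T cells were shifted down on the control array. Of 161 genes in 10 lists, 83 were lower, 17 higher and 61 not called, beside 6748 lower and 2799 higher of all 15115 genes; adjusted over the list alone, 86 were lower and 17 higher. Mature neutrophil genes had a median of −1.58 and platelet genes −1.26, each below all 10000 matched random lists, whose middles lay at −0.54 and −0.55. Of the neutrophil genes 8 were lower and 2 higher (9 and 2 adjusted over the list alone), the vanin VNN1 being higher by 3.88. Of the platelet genes 7 were lower and 4 higher (9 and 4 adjusted over the list alone). The ADP receptor P2RY12 differed by −3.77 and the chemokine PPBP by −2.92, while CLU (5.87) and SPARC (4.99), secreted proteins also made outside platelets, were higher. With the mean of the list genes the platelet value was −0.35 and the list was not shifted. T cell genes had a median of −0.86 (percentile 1.44), with 13 lower and 1 higher. Their shift was lost in 5 settings, such as probe sets with a high mean (−0.87) or quantile normalization again (−0.63). The other cell lists were not shifted as deposited: erythroid (−0.73, 15 lower and 1 higher, HEMGN by 3.32), B and plasma cell (−0.70, 11 lower and 1 higher), eosinophil and basophil (−0.75, 9 lower and 1 higher), monocyte (−0.70, 7 lower and 3 higher), NK and cytotoxic (−0.39, 7 lower and 0 higher), immature granulocyte (−0.62, 4 lower and 1 higher) and MHC class II (1.17, 3 higher and 2 lower). Other settings shifted 3 of these lists. Erythroid genes were shifted with low-level genes left out (−1.03, percentile 0.44) and with the mean of the list genes (−0.79), and B and plasma cell genes with the mean of all probe sets (−0.78, percentile 1.95). MHC class II genes were shifted with the mean of all probe sets (1.45), with the mean of the list genes (1.16), without foxes 9, 10 and 11 (1.59), and without fox 9 (1.27) or fox 11 (1.30), but their median fell to 0.10 after quantile normalization again.

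Lists of fatty acid oxidation, ribosomal proteins and oxidative phosphorylation were shifted up on the control array. Of 275 genes in 10 program lists, 118 were higher, 55 lower and 102 not called; adjusted over the list alone, 110 were higher and 55 lower. Fatty acid oxidation and lipid genes had a median of 2.49, with 14 higher and 4 lower, among them PDK4 (7.02), the kinase that restrains glucose oxidation, the fatty acid transporter CD36 (6.48) and ACADM (5.18). Ribosomal protein genes had a median of 2.31, with 23 higher and 1 lower (14 and 1 adjusted over the list alone), and oxidative phosphorylation genes 2.20, with 42 higher and 2 lower (43 and 2 adjusted over the list alone). After quantile normalization again these medians were 1.41 and 1.29, each above all 10000 random lists. The control array was near foxes 9, 10 and 11 on a quality control, the GAPDH 3' minus middle difference (−0.08, and 0.42 to 1.08 in these foxes), and these foxes also had the highest ribosomal and oxidative phosphorylation scores. Without them the medians were 2.89 and 2.52. On the control the 5' ends of the spikes lys, phe, thr and dap, transcripts added before labelling, also lay above all of foxes 1 to 8. For phe this was 6.60, against 5.24 to 5.79 in foxes 1 to 8 and 7.30 to 7.69 in foxes 9, 10 and 11. The spike 3' minus middle difference lay below foxes 1 to 8 for lys and phe and inside them for thr and dap. How much of the control difference goes with target preparation was not measured. RPL7 differed by 7.91, RPS12 by 5.63 and NDUFA13, of respiratory complex I, by 5.05. Cell cycle genes (0.73, 11 higher and 3 lower), interferon genes (0.20, 10 higher and 8 lower) and cholesterol synthesis genes (0.53, 8 higher and 5 lower) also lay above the outer bound of random lists. The mitotic kinase CDK1 differed by 3.76, IFI44L by 3.41 and MSMO1, of sterol synthesis, by 5.95. With low-level genes left out, the cholesterol median was −0.08, and the cholesterol, interferon and cell cycle lists were not shifted. The interferon shift was also lost with the mean of the list genes (0.45, percentile 96.53). The interferon median moved from 0.05 after quantile normalization again to 0.46 with centred arrays. With the mean of all probe sets per gene, medians were 1.53 for fatty acid, 0.46 for cell cycle and 1.32 for cholesterol genes. Inflammatory NF-kB genes (−0.75, 12 lower and 2 higher), immediate early genes (−0.72, 12 lower and 3 higher), glucocorticoid response genes (−0.71, 4 lower and 2 higher) and p53 genes (−0.47, 4 lower and 3 higher) were not shifted. NF-kB genes were shifted with low-level genes left out (−1.29, percentile 0.1), with the mean of all probe sets (−0.71), with the mean of the list genes (−0.75) and without any 1 of foxes 1, 2 and 3 (−0.77 to −0.78). The means of the glucocorticoid (0.12) and p53 (0.13) lists had the opposite sign. In all, 13 of 27 lists were shifted, 10 up and 3 down.

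The spread between foxes asks which genes differed among the 11 blood samples. DLA88, a class I antigen-presenting molecule of the dog, ran from 6.93 to 8.31 in foxes 1 to 8 and from 11.33 to 12.77 in foxes 9, 10 and 11. The myeloid receptor ADGRE3 ran from 7.72 to 9.75 and from 12.56 to 13.82, and the leukocyte tetraspanin CD37 from 7.09 to 7.99 and from 10.56 to 12.58. The most variable of the genes named by SD, NDUFAF4, an assembly factor of respiratory complex I, went the other way, at 12.44 in fox 1 and 6.26 in fox 9. Fox 2 (7.02) lay among foxes 9, 10 and 11 (6.26 to 7.38) in NDUFAF4.

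The 20 named variable genes had SDs between 1.78 and 2.37 (n = 11). In 13 of them foxes 9, 10 and 11 all lay above foxes 1 to 8, among them CORO1A (SD 1.90), an actin regulator of leukocytes, JAML (1.86), a leukocyte adhesion molecule, and CFD (1.86), complement factor D. The other 7 ran opposite, and in 2 of these all 3 foxes lay below. The same foxes stood apart on some of the array's quality controls: the GAPDH 3' minus middle difference was 0.54, 0.42 and 1.08 in foxes 9, 10 and 11, against 2.56 to 3.19 in foxes 1 to 8 and −0.08 on the control. Their actin 3' minus middle difference (4.40 to 5.11) lay inside that of foxes 1 to 8 (3.84 to 5.78). For EF1a, foxes 9 and 10 (3.06 and 3.07) lay inside foxes 1 to 8 (2.41 to 3.43) and fox 11 above (3.73). The first principal component of the foxes took 64.3% of the variance. In all, 6359 of 42924 probe sets (14.8%) had an SD of at least 0.5, and 3003 (7.0%) did within foxes 1 to 8. An SD of at least 1 was reached by 1289.

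**Figure D3:**
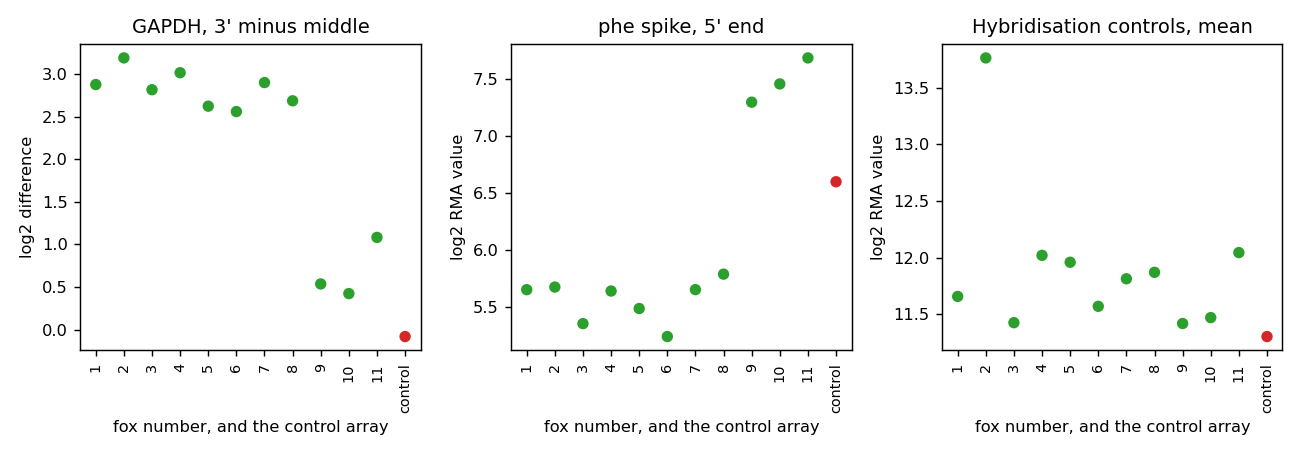
Quality controls of the 12 arrays by fox number, with the control last, as log2 values. The GAPDH 3' minus middle difference lies between 2.56 and 3.19 in foxes 1 to 8 and between 0.42 and 1.08 in foxes 9 to 11, and fox 2 has the highest mean of hybridisation controls, 13.76.

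Genes known to respond to PCBs and metals were measured for 13 of the 17 named in advance. CYP1B1, a cytochrome P450 induced through the dioxin receptor AHR, had the widest spread within foxes 1 to 8 among AhR genes, from 7.08 in fox 4 to 10.01 in fox 7 (7.97 ± 0.89, SD, n = 11). AHR itself was even, at 7.28 ± 0.21 (SD, n = 11). MT2A, a metallothionein that binds zinc and mercury, ran from 6.80 in fox 2 to 9.05 in fox 8 (7.81 ± 0.57, SD, n = 11). GPX1, a selenium-dependent peroxidase, ran from 11.26 to 14.52.

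The AHR-induced TIPARP lay between 7.77 and 9.07 in foxes 1 to 8 and between 10.16 and 10.56 in foxes 9, 10 and 11. The thioredoxin reductase TXNRD1 lay between 8.54 and 9.18 and between 10.40 and 11.60. These are the foxes that stood apart on GAPDH. Means over 11 foxes with SDs were 8.57 ± 0.72 for the quinone reductase NQO1, 10.04 ± 0.69 for the metal sensor MTF1, 7.67 ± 0.33 for the haem oxygenase HMOX1, and 6.96 ± 0.39 and 7.38 ± 0.36 for GCLC and GCLM. They were 6.19 ± 0.27 for the cystine transporter SLC7A11 and 7.09 ± 0.33 for SELENOP. On the control array, limma called GCLC (1.84, adjusted p 0.0016) and SLC7A11 (−1.40, adjusted p 0.00103), and it called HMOX1 (−0.80) at an adjusted p of 0.0468. The HMOX1 call was lost with low-level probe sets left out, under both rescalings, or without any 1 of foxes 3 to 8 (adjusted p by limma from 0.0526 to 0.204). CYP1B1 (1.37, adjusted p 0.172) was called without fox 7 (1.58, adjusted p 0.0369). GPX1 (−2.85, adjusted p 0.00144) and MTF1 (−1.61, adjusted p 0.00197) were called by limma after quantile normalization again. Without foxes 9, 10 and 11 it called TXNRD1 (1.66, adjusted p 5.45e-05), MTF1 (−0.93, adjusted p 0.00192) and TIPARP (−0.98, adjusted p 0.0308). CYP1A1, AHRR, MT1 and GPX4 had no probe set with that single symbol. Without the exposure of each fox, none of these levels can be set against a dose.

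**Figure D4:**
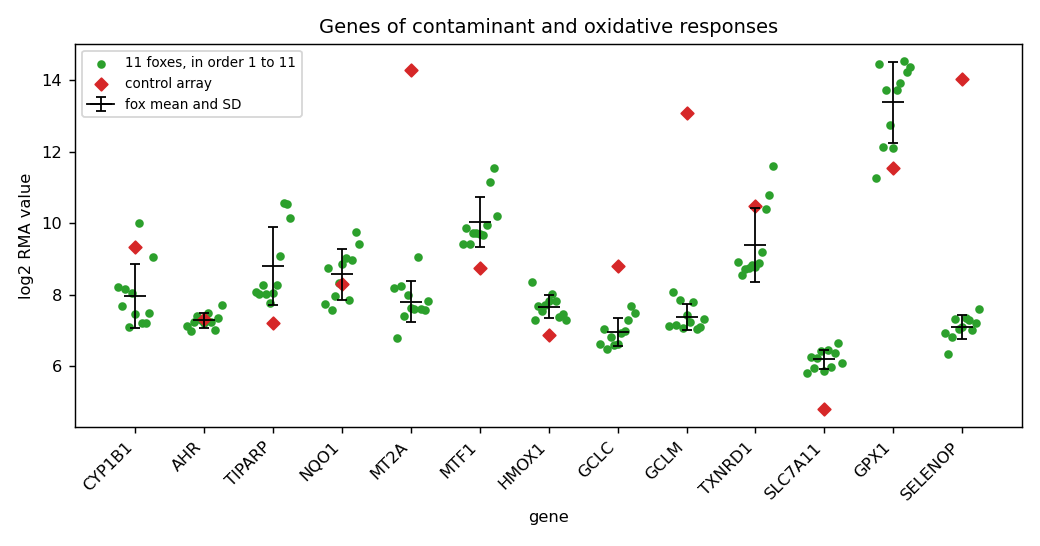
Points are the log2 RMA values of single arrays for 13 genes of contaminant and oxidative responses, with the 11 foxes and the control marked apart. MT2A, GCLM and SELENOP lie far higher on the control array, at 14.27, 13.08 and 14.04.

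Ribosomal protein genes varied together between foxes in every setting run, and 4 further lists did so as deposited. Of 27 lists, 5 had genes more correlated over the 11 foxes than random lists: erythroid (adjusted permutation p 0.0027), platelet (0.0027), ribosomal proteins (0.0027), oxidative phosphorylation (0.00473) and p53 and apoptosis (0.0448). The raw permutation p-values were 0.0003, 0.0002, 0.0001, 0.0007 and 0.0083 in this order, and 0.0001 is the smallest that 10000 random lists can give. None of the 7 exposure lists passed, heat shock genes being nearest (adjusted permutation p 0.0737). With the mean of all probe sets per gene, heat shock genes (adjusted permutation p 0.013) and NRF2 genes (0.0465) did pass. Within foxes 1 to 8 the mean correlation was 0.279 for erythroid, 0.465 for ribosomal and 0.330 for oxidative phosphorylation genes, with adjusted permutation p-values of 0.00135, 0.00135 and 0.0045. Platelet (0.212, adjusted permutation p 0.0634) and p53 genes (0.166, adjusted permutation p 0.143) did not pass there. The p53 list also missed without any 1 of foxes 1, 3, 4, 8, 9, 10 and 11 (adjusted permutation p from 0.0545 to 0.0747), and heat shock genes passed without fox 6 (adjusted permutation p 0.0419). The p53 list was also lost with Spearman correlation (adjusted permutation p 0.0589) and with the mean of all probe sets (0.245). With random lists also matched on SD, platelet genes (adjusted permutation p 0.0767) and oxidative phosphorylation genes (0.145) did not pass. Removing the first component, a setting chosen after seeing the data, lowered the mean correlation of ribosomal genes from 0.593 to 0.121. That of oxidative phosphorylation genes fell from 0.334 to 0.080. Platelet (adjusted random-list p 0.0715) and p53 genes (0.564) did not pass there. Within foxes 1 to 8 the scores of 14 of 27 lists went with the SD of all values on an array, which ran from 1.61 to 1.79. For ribosomal proteins this relation had r = 0.944 (exact permutation p 0.000769, adjusted 0.00442) and rho 0.929 (exact permutation p 0.00223), and r was 0.980 without the 2 arrays farthest from the median. For erythroid genes it had r = 0.637 (exact permutation p 0.0932, adjusted 0.14) and rho 0.595 (exact permutation p 0.132), and r was 0.761 without those 2 arrays.

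Erythroid genes separated single foxes. The list score was highest in fox 2, at 0.51, and lowest in foxes 1 and 3, at −0.47 and −0.40. ALAS2 ran from 10.89 in fox 1 to 15.05 in fox 9, and STRADB from 8.17 in fox 3 to 12.25 in fox 2. In fox 2 the haem synthesis enzyme FECH (12.88), TRIM58 (13.43) and the biliverdin reductase BLVRB (10.70) were at their highest. Fox 2 also had the highest hybridisation controls. Without it the erythroid list passed with a lower mean correlation over the foxes, 0.116 in place of 0.199 (adjusted random-list p 0.0324).

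Ribosomal and mitochondrial genes followed the foxes that stood apart on GAPDH. Ribosomal protein scores lay between 1.03 and 1.32 in foxes 9, 10 and 11 and between −0.95 and 0.05 in foxes 1 to 8. Oxidative phosphorylation scores lay between 0.60 and 0.63 and between −0.61 and 0.22, but overlapped after quantile normalization again (0.00 to 0.21 and −0.17 to 0.17). As deposited, 17 of 27 lists had the scores of foxes 9, 10 and 11 all above foxes 1 to 8, and 0 had them all below. Among them were NRF2 genes (0.55 to 0.68 and −0.51 to 0.08), MHC class II genes (0.59 to 0.85 and −0.65 to 0.07), neutrophil genes (0.29 to 1.01 and −0.52 to 0.13) and platelet genes (0.51 to 0.79 and −0.54 to 0.21). Quantile normalization again left smaller gaps for ribosomal (0.55 to 0.76 and −0.46 to 0.04), NRF2 (0.21 to 0.28 and −0.25 to 0.05) and MHC class II scores (0.20 to 0.36 and −0.35 to −0.01). Neutrophil (0.12 to 0.66 and −0.34 to 0.11) and platelet scores (0.23 to 0.54 and −0.39 to 0.22) were then barely apart. Heat shock scores, apart as deposited, then overlapped (−0.06 to 0.23 and −0.20 to 0.35). After quantile normalization again 1 of the 5 called lists passed, ribosomal proteins. Adjusted random-list p-values were then 0.0641 for erythroid, 0.0576 for platelet, 0.72 for p53 and 0.772 for oxidative phosphorylation genes. The mean correlation of erythroid genes was then 0.178.

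**Figure D5:**
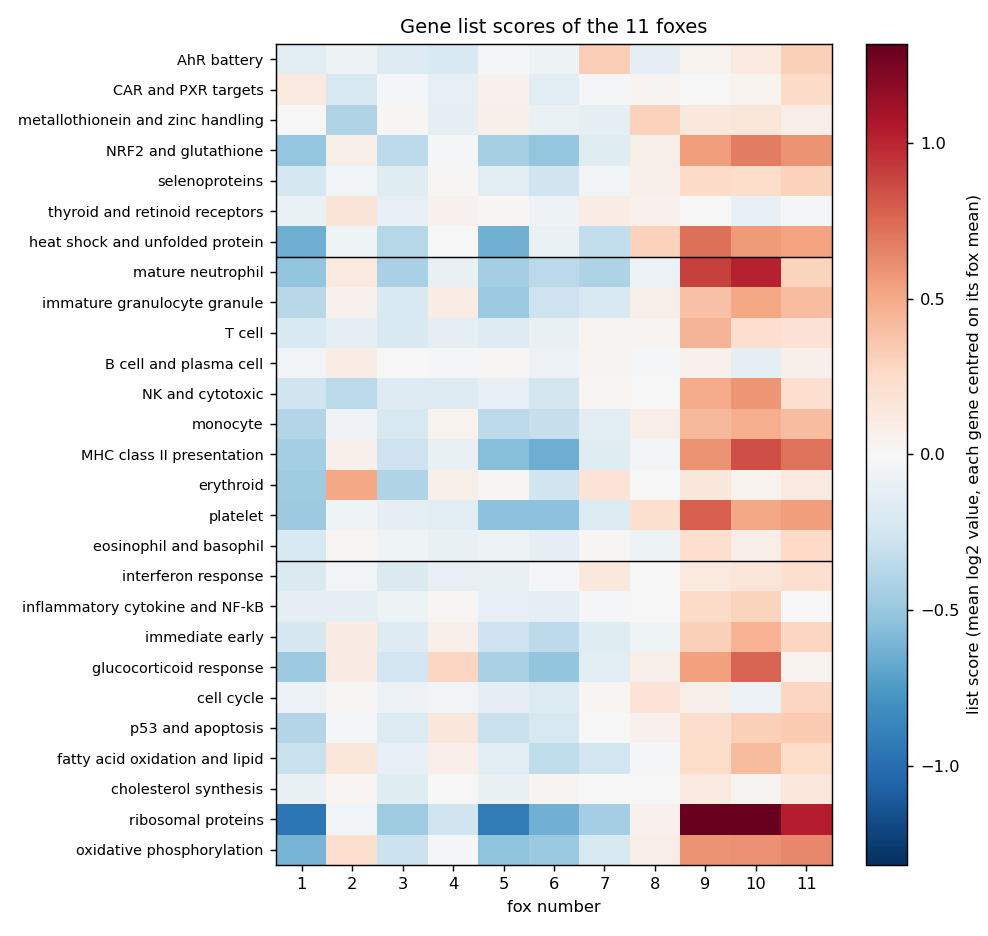
Colours give the score of each gene list (mean log2 value, each gene centred on its fox mean) in each of the 11 foxes. Ribosomal protein scores lie between 1.03 and 1.32 in foxes 9 to 11, and the erythroid score is highest in fox 2, at 0.51.

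Exposure lists against blood cell lists asks whether contaminant response genes went with cell makeup. Within foxes 1 to 8 and in the values as deposited, 4 of 70 pairs passed, and none of the 4 passed after quantile normalization again. Thyroid and retinoid receptor genes went with erythroid genes (r = 0.978, exact permutation p 0.000198, adjusted 0.0139; Spearman rho 0.905, exact permutation p 0.00456, adjusted 0.0639). NRF2 and glutathione genes went with MHC class II genes (r = 0.949, exact permutation p 0.000942, adjusted 0.0272) and with monocyte genes (r = 0.947, exact permutation p 0.00117, adjusted 0.0272). Selenoproteins also went with monocyte genes (r = 0.924, exact permutation p 0.00194, adjusted 0.0339). Spearman's rho was 0.952, 0.905 and 0.857 for these last 3 pairs. Without the 2 foxes farthest from the median cell score, r was 0.981, 0.978, 0.954 and 0.833 for the 4 pairs in this order. No pair passed the adjusted threshold by Spearman's rho within foxes 1 to 8. After quantile normalization again 0 of 70 pairs passed there, with 6 at an unadjusted p under 0.05, and r for the 4 pairs was 0.755, 0.689, 0.383 and −0.01 (adjusted exact permutation p from 0.475 to 0.988). With arrays centred on their medians 4 passed. Scores of the NRF2 (r = 0.958, rho 0.857) and monocyte lists (r = 0.987, rho 0.976) went with the SD of all values on an array (exact permutation p 0.00146 and 0.0107 for NRF2, 0.000124 and 0.000397 for monocyte genes; adjusted p of r 0.00659 and 0.00167). Without the 2 arrays farthest from the median r was 0.957 and 0.994. Scores of MHC class II genes (r = 0.901, exact permutation p 0.0058, adjusted 0.0165) also went with this SD. Those of selenoproteins did too (r = 0.896, exact permutation p 0.0061, adjusted 0.0165). Thyroid and retinoid genes (r = 0.682, adjusted exact permutation p 0.113) and erythroid genes (r = 0.637, adjusted 0.14) did not pass this test. Over all 11 foxes 26 of 70 pairs passed, all positive. No pooled r is given, since foxes 9, 10 and 11 stood apart, and without them 4 pairs passed. After quantile normalization again 12 passed, 6 positive and 6 negative.

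Single foxes against the others gave a scale for the control array. Foxes 9, 10 and 11 stood apart together, so each of them was compared with a reference that held the others of this group. This widens the spread of the reference and can lower their counts, which do not measure how far these foxes stood apart. Fox 2 had the most probe sets called by limma, 37 (29 higher and 8 lower), then fox 10 with 15, fox 11 with 3, fox 9 with 2 and fox 3 with 1. The other 6 foxes had 0, with between 281 and 2107 probe sets at an unadjusted p under 0.05. With low-level probe sets left out the highest count was 2, and without foxes 9, 10 and 11 it was 214.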

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

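The tests of foxes 9, 10 and 11 in this part were chosen after the result was seen. Signals outside the main measurement stood above the control array in 2 kinds of array control. The hybridisation controls, labelled targets added to every array, averaged 13.76 over 27 probe sets on the array of fox 2, against 11.42 to 12.05 on the other fox arrays and 11.30 on the control array. The 5' end of the phe spike, a transcript added to the RNA before labelling, stood at 7.69 in fox 11, against 6.60 on the control array.

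Foxes 9, 10 and 11 stood apart from the other 8 in gene expression and in the spikes. The phe 5' end was at 7.30, 7.46 and 7.69 in these foxes and between 5.24 and 5.79 in foxes 1 to 8. For 3 of 4 spikes, which were never in the blood, the 3' minus middle difference lay below all of foxes 1 to 8. This argues against degradation of the blood RNA before labelling and another share of blood cell types for the spike part only. The 3 foxes had been set apart on such array controls, so the spikes were not an independent check. They cannot decide the cause of the gene expression part. A difference in labelling or target preparation between arrays may account for part of the pattern, since the same 3 of 4 spikes have the change that it needs. Another share of blood cell types behind the gene expression part stays open, as does degradation: the lowest cell list, eosinophil and basophil, had a median signed SD along the first component of −0.11, neutrophil genes had 0.59, and ribosomal genes 0.77 with quartiles of 0.37 and 1.23. Exposure, age, sex and origin of single foxes are not in the labels and were not tested.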

How the results depend on the processing

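The settings without foxes 9, 10 and 11, with foxes 1 to 8, without fox 2 and with the first component removed were chosen after the result was seen. No paired analysis was possible because the labels pair no samples. Among the planned settings, probe sets called for the control array numbered 11816 with a log2 difference of at least 1 and 12802 with low-level probe sets left out, where fewer were tested; leaving out each fox gave 25001 to 27620. Lists that varied together numbered 1 after quantile normalization again, 9 with the mean of all probe sets, 3 with random lists also matched on SD and 3 without foxes 9, 10 and 11, with 4 to 6 on leaving out each fox. Pairs of exposure and cell lists numbered 12 after quantile normalization again, 15 with scaled genes and 4 without foxes 9, 10 and 11, where centred arrays gave 4 and quantile normalization again 0, with 24 to 27 on leaving out each fox. Variable probe sets numbered 1289 at an SD of at least 1, a stricter threshold, and 3003 without foxes 9, 10 and 11, with 5627 to 6650 on leaving out each fox. The highest count for a single fox was 18 at a log2 difference of at least 1, 2 with low-level probe sets left out, 20 after quantile normalization again, 214 without foxes 9, 10 and 11, and 8 without fox 2. Lists shifted on the control array numbered 9 with low-level genes left out, where the CAR and PXR and the B and plasma cell lists were not tested. They numbered 12 after quantile normalization again, 15 with the mean of the list genes and 12 without foxes 9, 10 and 11. Leaving out each fox gave 13 to 14 shifted lists. Among the lists shifted as deposited, reversed medians were those of NRF2 after quantile normalization again (−0.13) and with the mean of all probe sets (−0.18), and of cholesterol synthesis with low-level genes left out (−0.0802). Except where fewer probe sets or foxes or a stricter threshold explain a count, the cause was not tested. Of the named genes' control differences over the settings, 2126 values stayed called or stayed not called, 25 gained the call and 41 lost it. Direction was checked only for genes called as deposited. No background level was given, so values near the lowest, 3.23, could not be told from background signal.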

Other observations

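The lists of organ markers, the tests of organ RNA and of canine match, and the removal of the first component were chosen after the result was seen. So was EIF2S3. Single genes of the fixed lists differed between foxes, though the immature granulocyte, NK and cytotoxic, interferon, NF-kB and immediate early lists did not pass the test of varying together as planned, with 1 probe set per gene. Interferon genes passed with the mean of all probe sets (adjusted random-list p 0.0332), and NK and cytotoxic genes with the first component removed (adjusted random-list p 0.00405). T cell (0.0324) and cell cycle genes (0.0124) also passed with that component removed. T cell genes passed with centred arrays (0.0279) and with the mean of all probe sets (0.023) too. Neutrophil (0.0489) and monocyte genes (0.0445) passed with low-level genes left out. Lactoferrin (LTF), of neutrophil granules, ran from 8.54 in fox 5 to 13.78 in fox 10, and within foxes 1 to 8 it reached 11.98 in fox 8. The cytotoxic protease GZMB lay between 6.91 and 8.57 in foxes 1 to 8 and between 9.89 and 11.48 in foxes 9, 10 and 11, and the interferon-induced MX2 between 6.89 and 7.77 and between 8.99 and 9.97. Fox 4 had the highest FOS, an immediate early gene, among foxes 1 to 8 (12.51, against 9.26 in fox 6), and the highest IL1R2, the decoy receptor of interleukin 1, of all 11 foxes (11.81).

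An SD of at least 0.5 over the foxes was reached by 43 of 54 ribosomal protein genes, 36 of 58 oxidative phosphorylation genes and 12 of 19 heat shock genes. It was reached by 8 of 13 glucocorticoid response genes, among them TXNIP (SD 1.37) and TSC22D3 (SD 1.02), and by 11 of 17 mature neutrophil genes. It was reached by 1 of 19 thyroid and retinoid receptor genes and 1 of 14 B and plasma cell genes. Lists were not tested against each other for these counts. EIF2S3, a subunit of a translation initiation factor, had 1 probe set between 5.74 and 7.09 in foxes 1, 2, 4, 5, 9 and 11 and between 9.58 and 11.31 in foxes 3, 6, 7, 8 and 10. Its other 2 probe sets did not part the foxes in this way.

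The control array stood apart from the foxes, with liver, gut and muscle genes high and neutrophil genes low. Better match of canine RNA to canine probes as the whole cause is argued against by the neutrophil median of −1.58, since such a match would raise blood genes too. The neutrophil list holds S100A8, S100A9 and PGLYRP1, already seen among the lowest genes, so it was not an independent check. The difference in target preparation that parts the foxes is argued against as the whole cause by a correlation, across genes, of 0.19 between the control difference and the first fox component; genes are not independent replicates. RNA of several solid tissues on the control array may account for the pattern: 3 of 13 organ lists had a median above 2, liver (3.77), skeletal muscle (3.27) and intestine (4.93), with ALB at 15.30, MYH2 at 14.31 and SI at 15.13. This stays open, since 13 of the 90 genes had been seen among the extremes, and with the 77 others 1 list stayed above 2, intestine at 2.16 (percentile 99.65 of random lists), with liver at 1.59 (99.72), muscle at 1.30 (99.25) and stomach at 0.77 (97.52). Leaving out genes for their large differences lowers such medians by itself, so the bound of 2 could not decide.

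The remaining organ lists had lower medians. Stomach genes stood at 1.75, lung genes at 1.06, testis genes at 0.16, adipose genes at 0.08 and kidney genes at −0.03. Brain genes stood at −0.24, heart genes at −0.42, pancreas genes at −0.50, adrenal genes at −0.63 and thyroid genes at −0.92. Of the 90 genes, 33 had a fox mean above that of the median gene, and 4 were also in the fixed lists.

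Genes with a fox mean above that of the median gene, an SD of at least 1 and a correlation with the first component below −0.7 are called opposite genes here. They numbered 32, among them NDUFAF4, SNX13, CRISPLD2, PEX19 and HCFC1. The adipocyte hormone gene ADIPOQ (12.12 in fox 1 and 8.95 in fox 9) and the chemokine CCL20 (13.56 and 10.82) were also among them. Fox 2 (9.59 and 10.83) lay among foxes 9, 10 and 11 in ADIPOQ and CCL20. A change of the gene itself predicts that other probe sets of the same genes run along, but 33 such probe sets of 21 genes had a median correlation of −0.19 with the named probe set. For genes with a correlation above 0.7 and otherwise the same bounds, 343 other probe sets had a median of 0.83. The test stays open, because the 95% bootstrap interval of the first median, added after its value was seen, ran from −0.56 to 0.39, and the other probe sets varied little (median SD 0.25). Whether the probes of the opposite genes target unusual parts of the transcripts was not tested.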
